A study of Mus musculus with 7 samples.

How the data were processed

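RNA from mouse spleen was measured by bulk RNA sequencing in 7 libraries, which the labels describe as sorted follicular helper T (Tfh) cells from animals sensitised with ovalbumin by intraperitoneal injection. Per the labels, 3 libraries came from wild-type mice and 4 from mice with the genotype Mst1 knockout, and each replicate is called a biological replicate. The titles of the 4 write the genotype as Mst1∆CD4, a form used for a deletion restricted to cells that express Cd4 or descend from such cells. Per the labels' protocols, total RNA was purified with a Qiagen column kit and libraries were made with an NEBNext Ultra kit. The aligner, the counting tool, the annotation release and the strand setting were not given in the sources used here. The genome build is GRCm38 (mm10), per the submitters' processing notes.

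The deposited table holds, per the file headers, a read count and an FPKM value for each gene in each library, and the result of the authors' own comparison. The counts are whole numbers per gene, with no normalization, in 54532 genes, of which 25641 had no count in any library. Totals ran from 16789158 to 18375275 counts per library. The deposited FPKM values equal the counts divided by gene length and by 1 factor per library, with a relative spread of that factor within a library of at most 1.6e-08. The authors' comparison gives a mean signal for each side, a log2 fold change, a p-value and an adjusted p-value, per the file headers. The headers name the sides of that comparison with codes, VPA and VPC. The 2 deposited means were rebuilt from the counts of the 4 knockout libraries and of the 3 wild-type libraries over 26683 genes, which fixed the side of each. The authors' test and its adjustment were not given in the sources used here. Of the gene identifiers, 54409 were also in GENCODE release M21, and 98.3% of these had the same coordinates there. Coordinates in the text are those of the deposited table.

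The comparison was fitted to the counts with edgeR 4.0.16 in R 4.3.3, using TMM normalization, filterByExpr with its default settings, and the robust quasi-likelihood F-test with genotype as the only term. All 7 libraries entered. P-values were adjusted with the Benjamini-Hochberg method over the 15795 genes tested, and a gene was called at an adjusted p under 0.05. Levels are CPM, the counts of a gene scaled to a common library size with TMM, as mean ± SD, and fold changes are knockout over wild type with the standard error (SE) on the log2 scale. Single values were compared with a two-sided exact permutation test over the 35 splits of 7 libraries into 3 and 4, whose smallest possible p is 0.0286. A group with no count of a gene was given a floor of 3 counts per library, and with 1 to 3 counts a ratio with an exact 95% interval. Such intervals and floors cover counting error only.

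The test, the alternatives, 30 gene lists and the rule for named genes were fixed before the data were examined. Lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, two-sided, with an inter-gene correlation of 0.01, and adjusted over the 30 lists. The same test with an estimated correlation and the directional fry test were run beside it. Of the 574 genes in the lists, 573 were in the table, and 1 gene stands in more than 1 list. In the glycolysis list, 2 gene identifiers share the symbol Aldoa. The rule named Stk4 and Stk3, then in each direction the 10 genes with the largest fold change among those called with a mean of at least 1 CPM and no overlap between groups, leaving out predicted models, pseudogenes and antigen receptor segments. It also named up to 4 members of each list with the smallest p, or up to 8 where more than 4 were called. Some of these are described, and others are not reported here. A further 10 lists were added after the data were seen and are used in the closing observations.

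On simulated counts with the means and library sizes of these 7 libraries, the edgeR step recovered 67% of 100 genes changed by 1 log2 unit and 95% of 100 genes changed by 2, with 19 false calls among 15488 genes, which were 10.5% of its calls and above the nominal 5%. The changed genes were drawn from those with an average log2 CPM above 1, so recovery at lower levels was not measured. A false share depends on the number of changed genes, so 10.5% need not hold for the real calls. In the list step, 5 of 200 random lists had p under 0.05. The simulated genes varied independently, so this could not show how the list step behaves for correlated genes. The estimated correlation within the real lists reached 0.82. Alternatives were DESeq2 1.42.0, limma-voom with quality weights, 3 other scalings, 2 other filters, a fit that was not robust, a replicate block, protein-coding genes alone, 3 fits to log2 FPKM with a pseudocount of 1 or 0.1, a test against a fold change of 1.5 and the removal of each library in turn. Replicates were compared before averaging, and no pair of libraries agreed within sampling noise (chi-square of at least 21.7 per gene). Figures were drawn with matplotlib 3.10.9. Genes with near-identical copies elsewhere, such as Rpl29, Hspa1a, Gbp2b and the haemoglobin and immunoglobulin genes, have uncertain counts, since the treatment of shared reads was not given in the sources used here. The same holds for genes that overlap a gene on the other strand.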

Results

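The study asked how the Hippo pathway kinase MST1 bears on follicular helper T cells, the CD4 T cells that help B cells in germinal centres. Gene expression was measured in spleen cells of ovalbumin-sensitised mice, in 3 libraries labelled wild type and 4 labelled Mst1 knockout, with Mst1∆CD4 in their titles. Each library held between 16789158 and 18375275 counts. Spearman correlations of log2 CPM ran from 0.985 to 0.989 among the wild-type libraries, from 0.973 to 0.986 among the knockout libraries and from 0.944 to 0.97 between the groups. The first principal component held 52.7% of the variance and separated the groups (exact permutation p = 0.0286, the smallest the design can give). Along the second component, with 16.2% of the variance, knockout replicate 4 lay at 45 and the other knockout libraries between -33.5 and -12.3. Wild-type replicate 1 lay at 27.1, on the side of knockout replicate 4, and wild-type replicates 2 and 3 at -12.2 and -1.7. This component did not separate the groups (exact permutation p = 0.714).

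The gene of the kinase named by the study was read first. MST1 is encoded in the mouse by Stk4 (ENSMUSG00000018209, chromosome 2, 164070322 to 164155524, plus strand). Stk4 stood at 327 ± 10.1 CPM (SD, n = 3) in the libraries labelled wild type and 293 ± 7.34 CPM (n = 4) in those labelled knockout. All knockout libraries lay below all wild-type libraries (exact permutation p = 0.0286), which did not hold for CPM by total library size (exact permutation p = 0.0857), while the log2 fold change of -0.16 (SE 0.08) did not pass the test over all genes (edgeR adjusted p = 0.225). Its 95% interval ran from -0.37 to 0.05, so a loss of most Stk4 counts is outside it. The counts are per gene, and reads outside a deleted part would also be counted. With a deletion restricted to the CD4 lineage, as the titles have it, so would the reads of B cells and myeloid cells. The paralog Stk3, which encodes MST2 (chromosome 15), stood at 11.8 ± 2.53 CPM (n = 3) and 16.3 ± 3.48 CPM (n = 4), with an adjusted p of 0.15. Another gene carries the symbol Mst1, for macrophage stimulating 1 (ENSMUSG00000032591, chromosome 9, 108080436 to 108085003). It was looked at after its values were seen, and it fell from 9.41 ± 2.08 to 1.39 ± 0.42 CPM (log2 fold change -2.75, adjusted p = 0.000844). Because Stk4 did not separate the labels by more than this, which gene was deleted is not settled by these values, and groups are named by their labels throughout.

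The libraries held abundant transcripts of cells other than T cells. Among the genes with the highest mean level in the wild-type libraries were Ighm at 9770 CPM, Igkc at 5580 CPM and Cd74 at 5360 CPM, which B cells express. Lyz2 at 4690 CPM, Ngp at 4100 CPM and S100a9 at 4080 CPM, genes of myeloid cells, were also among them. The T cell receptor component gene Cd3e stood at 45.7 ± 9.28 CPM (n = 3), and the B cell receptor component gene Cd79a at 833 ± 218 CPM. In the knockout libraries Cd3e was at 11.4 ± 5.61 CPM (n = 4) and Cd79a at 411 ± 138 CPM. The ratio of Cd79a to Cd3e lay between 12.8 and 49.3 in the 7 libraries. These markers were chosen for display after their values were seen.

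**Figure D1:**
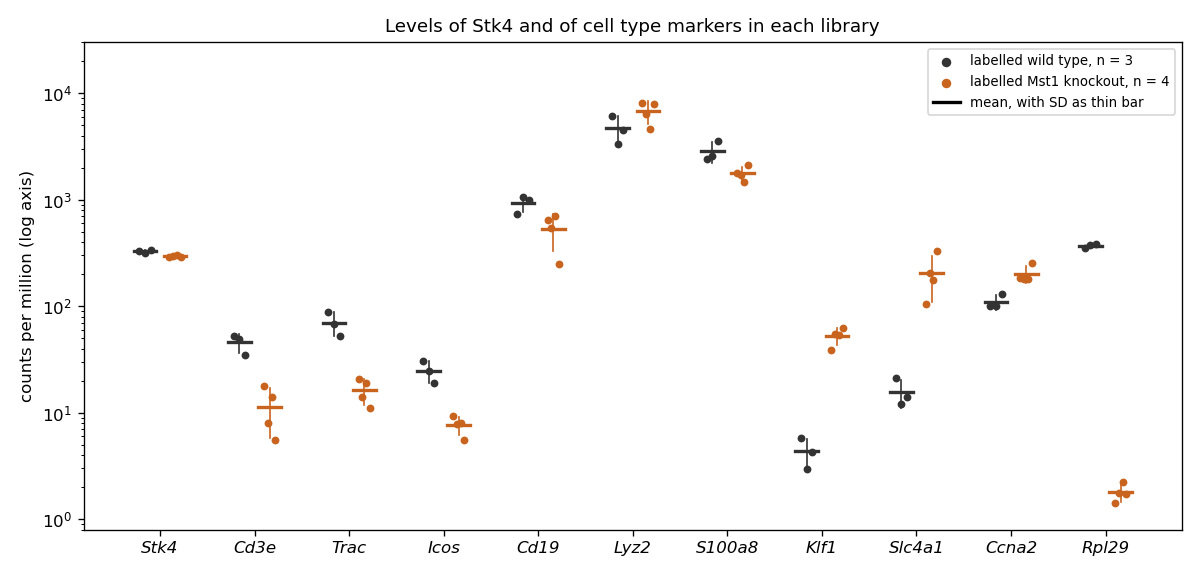
Levels in CPM on a log axis for 11 genes, with a point per library, the mean as a thick line and the SD as a thin bar, for 3 libraries labelled wild type and 4 labelled Mst1 knockout. Stk4 lies at 327 and 293 CPM on average, T cell genes such as Cd3e are lower in the knockout libraries, and erythroid genes such as Klf1 are higher.

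Across the transcriptome, 2455 of 15795 tested genes passed an adjusted p of 0.05 (edgeR), with 1376 higher and 1079 lower in the knockout libraries. Of these, 623 were at least 1 log2 unit higher and 483 at least 1 log2 unit lower. The median log2 fold change of all tested genes was -0.002. The groups did not overlap for 4746 of the tested genes, where chance gives 5.7% of genes. The count depended on single libraries. It was 1326 (848 higher, 478 lower) without wild-type replicate 1 and 1050 (639 higher, 411 lower) without wild-type replicate 2. It was 1161 (691 higher, 470 lower) without wild-type replicate 3 and 1384 (835 higher, 549 lower) without knockout replicate 2. In the authors' deposited table, 3329 genes had an adjusted p under 0.05, with 1851 higher and 1478 lower, and 2444 of the 2455 genes called here were among them, each in the same direction.

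**Figure D2:**
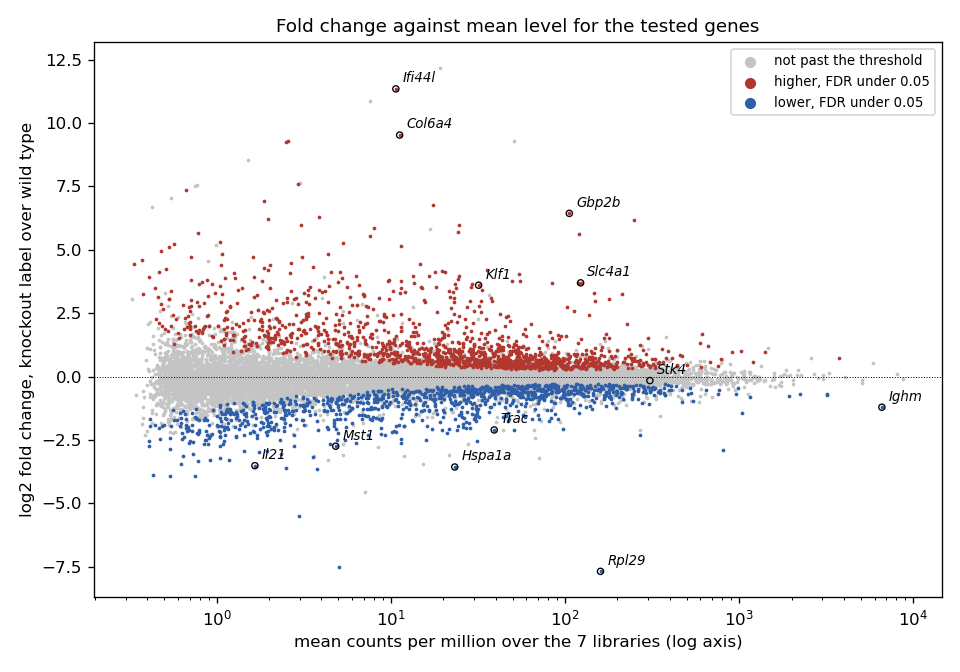
Log2 fold change of the knockout label over wild type (n = 4 and 3) against mean CPM on a log axis, with a point for each of the 15795 tested genes. The 1376 genes called higher are red and the 1079 called lower are blue, and fitted values of genes with few counts in a group, such as Ifi44l, depend on the prior count.

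Of the 10 named genes with the largest rises, 7 had at most 3 counts in the wild-type libraries together. Ifi44l, an interferon-induced gene on chromosome 3, had 0 counts in the wild-type libraries and 18.7 ± 5.91 CPM in the knockout libraries, at least 107-fold higher (adjusted p = 0.000526). Col6a4, a collagen gene (chromosome 9, 105989454 to 106096783), had 1 count in the wild-type libraries and 1393 in the knockout libraries, a ratio of 1010 (95% interval 181 to 39900). Sycp1, a gene of the meiotic synaptonemal complex, was at least 25.8-fold higher and the kallikrein gene Klk1b22 at least 25-fold higher, both with 0 wild-type counts. The guanylate-binding protein gene Gbp2b rose from 2.12 ± 0.73 to 184 ± 176 CPM, with 435 CPM in knockout replicate 2 and 27.6 to 148 CPM in the other knockout libraries. Cpne4 and Cnnm1, each with 2 wild-type counts, had ratios of 87.8 (24 to 729) and 46.8 (12.7 to 391). Slc2a4, which encodes the glucose transporter GLUT4, had 3 wild-type counts and a ratio of 31.7 (10.6 to 156). The kinase gene Hunk was 62.6-fold and Apol11a 38-fold higher as fitted, from wild-type means of 0.076 and 0.23 CPM. Over the alternatives, the log2 fold change ran from 0.68 to 6.34 for Hunk and from 2.31 to 6.20 for Apol11a. These include fits to log2 FPKM, whose pseudocount shrinks differences of genes at low levels.

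In the other direction, Rpl29, a ribosomal protein gene (ENSMUSG00000048758, chromosome 9, 106429454 to 106431568), fell from 371 ± 18 CPM (n = 3) to 1.79 ± 0.33 CPM (n = 4), with an adjusted p of 2.07e-08. The mitochondrial gene mt-Nd3 fell from 7.96 ± 2.52 to 0.64 ± 0.41 CPM, by 3.63 on the log2 scale, and the inducible heat shock gene Hspa1a by 3.57. Il21, the cytokine typical of Tfh cells, fell from 3.47 ± 0.66 to 0.30 ± 0.19 CPM (log2 fold change -3.52, SE 0.45, adjusted p = 0.00212). The growth factor gene Bmp7 fell by 3.29, and Cd209a, a lectin gene of dendritic cells and monocytes, by 3.18. Tgfb1i1, Tmie, Ntrk3 and Tmem121b had log2 fold changes between -3.06 and -2.93. The knockout means of these genes and of Bmp7 lay between 0.24 and 0.56 CPM, so their fold changes rest on few counts. Over the alternatives, with the fits to log2 FPKM among them, the value ran from -3.49 to -0.59 for Bmp7 and from -3.35 to -0.15 for Ntrk3.

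Genes of the Tfh program were lower in the knockout libraries. Of 28 tested members, 21 fell, none rose and 7 did not pass, with 22 lower and 1 higher when adjusted over the list alone. The median log2 fold change was -0.99 (camera adjusted p = 1.96e-09, and adjusted p = 0.506 with an estimated correlation). Icos, a co-stimulatory receptor needed for Tfh cells, fell from 24.9 ± 5.85 to 7.66 ± 1.55 CPM (adjusted p = 0.00187). Tox, a transcription factor, fell by 2.05 on the log2 scale and Cd40lg, the ligand through which T cells help B cells, by 2.31. Bcl6, the lineage-defining factor of Tfh cells that germinal centre B cells also express, fell from 116 ± 28.3 to 59.7 ± 2.48 CPM. The T cell receptor genes Cd3e and Trac fell beside them, by 2.01 and 2.11, and the T cell surface marker gene Thy1 by 1.61, chosen after their values were seen.

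Genes of regulatory T cells and of follicular regulatory T cells were also lower, with 12 of 18 lower and 2 higher (14 lower and 2 higher when adjusted over the list alone). The list passed at a camera adjusted p of 1.78e-05, with an adjusted p of 0.506 with an estimated correlation. Foxp3, their defining factor, fell from 14.6 ± 4.43 to 4.68 ± 0.11 CPM, Ctla4 fell by 1.95 and Ikzf2 by 1.29. The count of lower genes was 6 without wild-type replicate 1 and 5 without wild-type replicate 2. Itgae, which dendritic cells also express, rose from 11.7 ± 2.51 to 24.3 ± 3.55 CPM. Of the 20 genes of naive T cells, FOXO targets and lymphoid egress, 6 fell and none rose (11 lower and 1 higher when adjusted over the list alone). Here the camera adjusted p was 0.00157, and the adjusted p = 0.506 with an estimated correlation. The count of lower genes was 3 without knockout replicate 2, wild-type replicate 1 or wild-type replicate 3 and 2 without wild-type replicate 2. The interleukin 7 receptor gene Il7r fell by 1.43, Bach2 by 1.32, Foxo1 by 1.04 and Klf2, a regulator of lymphocyte egress, by 0.71. Of 22 immediate early and T cell receptor-induced genes, 5 fell, also 5 when adjusted over the list alone, at a camera adjusted p of 0.00199 and an adjusted p of 0.506 with an estimated correlation. The count was 3 without knockout replicate 1 or wild-type replicate 3, 2 without wild-type replicate 1 and 1 without wild-type replicate 2. The 5 included Cd69, which fell by 0.82, Egr2, which fell by 1.03, and Nr4a1, which fell from 208 ± 78.9 to 103 ± 17.9 CPM. Cd3e and Trac fell in the same libraries, and B cell genes had a median log2 fold change of -0.85, with 4 of 21 tested members above 0.

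The other T helper lists did not pass the test. Of 20 type 1 helper and cytotoxic genes, 3 fell and 2 rose (7 and 3 when adjusted over the list alone, camera adjusted p = 0.108). Gzmk fell by 1.79 and Stat4 by 0.95, while Ly6c2, a surface antigen also found on monocytes, rose from 583 ± 156 to 1150 ± 355 CPM. Of 8 type 2 helper genes, 2 fell and 1 rose (5 and 1 when adjusted over the list alone, adjusted p = 0.125). Ccr4 fell by 2.12 and Gata3 by 1.5, and Il1rl1, the receptor for interleukin 33, rose by 1.75. Of 7 type 17 helper genes, 1 fell, Rora, by 0.71 (also 1 when adjusted over the list alone, adjusted p = 0.252). Of 12 co-inhibitory genes, 5 fell and 1 rose, the same counts as when adjusted over the list alone (adjusted p = 0.108). Nt5e, which encodes CD73, fell by 2.07 and Cd5 by 1.53, and Lilrb4a, a receptor of myeloid cells, rose by 1.06. Without wild-type replicate 3, the type 1 list reached an adjusted p of 0.028, the type 2 list 0.0121 and the co-inhibitory list 0.0199, each lower in the knockout libraries.

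Cell cycle genes were higher in the knockout libraries. Of 35 tested members 21 rose and none fell, with 30 higher when adjusted over the list alone. Their median log2 fold change was 0.58 (camera adjusted p = 1.51e-09, and adjusted p = 0.506 with an estimated correlation). The count of higher genes was 9 without knockout replicate 2, 4 without wild-type replicate 1, 4 without wild-type replicate 2 and 12 without wild-type replicate 3. The replication licensing gene Cdc6 rose from 32.3 ± 2.35 to 66.7 ± 13.7 CPM (n = 3 and 4, adjusted p = 0.00404). Tyms, which encodes thymidylate synthase, rose by 1.13 on the log2 scale, and the cyclin gene Ccna2 rose from 110 ± 17.6 to 200 ± 36.3 CPM. Erythroid genes rose in the same libraries, with a median log2 fold change of 3.29.

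Genes of oxidative phosphorylation were slightly higher as a list, with 6 of 33 members higher and none lower (7 when adjusted over the list alone). The median log2 fold change was 0.28 (camera adjusted p = 0.000142, and adjusted p = 0.549 with an estimated correlation). The count of higher genes was 10 without knockout replicate 3, 2 without knockout replicate 1 or wild-type replicate 2, 1 without knockout replicate 2 or wild-type replicate 3 and 0 without wild-type replicate 1. The erythroid genes, with their median of 3.29, rose in the same libraries as these genes and those of glycolysis. The succinate dehydrogenase gene Sdhc rose by 0.46 and the ATP synthase gene Atp5b from 639 ± 38.5 to 845 ± 72.0 CPM. Of 25 glycolysis and hypoxia genes, 5 rose and none fell, as when adjusted over the list alone (adjusted p = 0.105). The lactate transporter gene Slc16a1 rose by 1.25 and the hexokinase gene Hk1 by 0.77. The list reached an adjusted p of 0.028 without knockout replicate 3. Of 21 cholesterol synthesis genes, 2 rose and 2 fell, as when adjusted over the list alone (adjusted p = 0.847), with Mvd higher by 0.53 and Sc5d at -0.49. Among 19 genes of the amino acid and integrated stress response, 1 rose, Asns, which encodes asparagine synthetase, by 1.76, also 1 when adjusted over the list alone (adjusted p = 0.863). Ddit4 of that list had a log2 fold change of -0.94 that did not pass (adjusted p = 0.0575). None of 18 endoplasmic reticulum folding genes passed edgeR's test, over all genes or adjusted over the list alone (list adjusted p = 0.617). Canx of that list had a log2 fold change of 0.32 (adjusted p = 0.0826).

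In the Hippo pathway, 2 of 19 genes fell and none rose, with 1 lower when adjusted over the list alone (camera adjusted p = 0.108). They were Vgll4, a cofactor of the TEAD transcription factors, which fell from 60.4 ± 3.32 to 43.5 ± 2.86 CPM, and Rassf2, which binds MST kinases and fell by 0.37. Of 26 adhesion and migration genes, 5 fell and 1 rose, as when adjusted over the list alone (adjusted p = 0.108). The integrin gene Itga6 fell by 1.10, and Ccr2, a chemokine receptor of monocytes, rose from 270 ± 104 to 874 ± 202 CPM. This list reached an adjusted p of 0.0492 without wild-type replicate 3. Of 30 interferon-stimulated genes, 2 rose and 1 fell, with 2 and 0 when adjusted over the list alone (adjusted p = 0.944). Ifi44, the neighbour of Ifi44l, rose by 2.03, and Ddx58, which encodes the RNA sensor RIG-I, fell by 0.63. The median of this list was -0.17 and its mean 0.38, which became 0.23 with Ifi44l at its bound, while the test's direction was down. The mean was 0 without Ifi44l. The median was 0.05 without knockout replicate 3, 0.02 without wild-type replicate 1, -0.27 without wild-type replicate 3 and -0.38 without knockout replicate 1, where 5 genes were lower. Of 22 apoptosis genes, 2 rose, as when adjusted over the list alone (adjusted p = 0.936), among them the cell cycle inhibitor gene Cdkn1a, by 1.00. The median of that list was -0.01 and its mean 0.03, and the median was 0.01 without TMM, 0.01 without knockout replicate 4 and 0.02 without wild-type replicate 1. Of 22 genes of JAK-STAT signalling and cytokine receptors, 4 fell and 2 rose, as when adjusted over the list alone (adjusted p = 0.383). Il21r, the receptor for interleukin 21, fell by 0.99 and Jak1 by 0.38, and Tyk2 rose by 0.42.

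**Figure D3:**
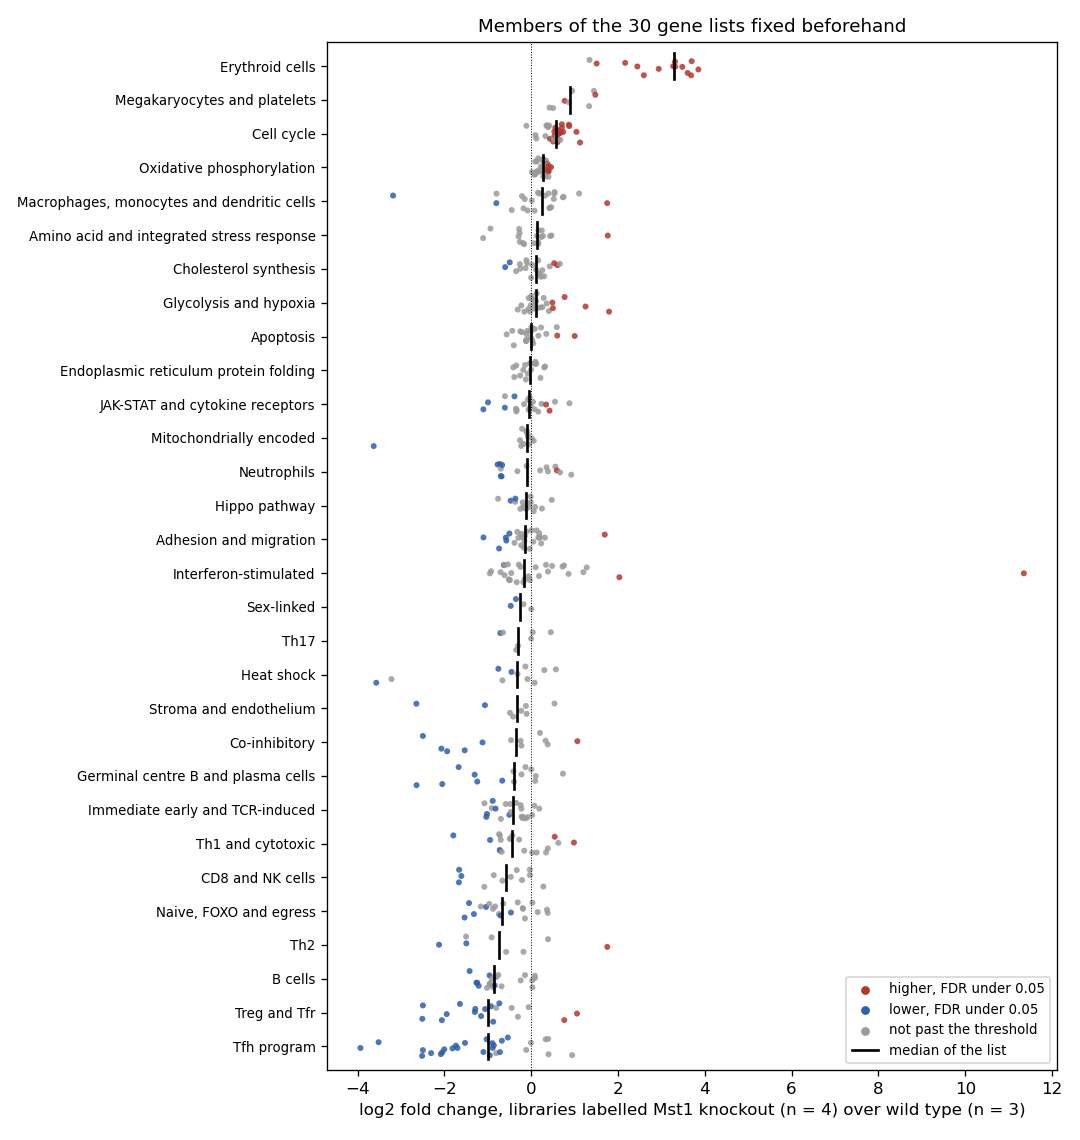
Log2 fold change of each tested member of the 30 fixed gene lists, knockout label (n = 4) over wild type (n = 3), with the list's median as a black bar and genes past an adjusted p of 0.05 in red or blue. The erythroid list has a median of 3.29 and the Tfh program a median of -0.99, and the far right point of the interferon list is Ifi44l, which had 0 wild-type counts.

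Markers of other cell types moved with the labels. Erythroid genes rose, with 13 of 14 tested members higher, as when adjusted over the list alone (camera adjusted p = 5.37e-12, and adjusted p = 0.506 with an estimated correlation). Klf1, the master regulator of red cell development, rose from 4.33 ± 1.39 to 52.7 ± 9.87 CPM (adjusted p = 0.000267). The anion exchanger gene Slc4a1 rose by 3.70 on the log2 scale and the carbonic anhydrase gene Car2 by 3.27. Of 8 megakaryocyte and platelet genes, 2 rose, with 4 when adjusted over the list alone (camera adjusted p = 0.00526, and adjusted p = 0.506 with an estimated correlation). The count was 1 without knockout replicate 1, knockout replicate 2, knockout replicate 3 or wild-type replicate 2 and 0 without wild-type replicate 1 or wild-type replicate 3. Itga2b rose by 0.77, and Pf4 had a log2 fold change of 1.33 that did not pass over all genes (adjusted p = 0.0603).

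B cell genes were lower. Of 21 tested members 6 fell and none rose, with 13 lower when adjusted over the list alone, and their summed level was 32445 ± 3849 CPM (n = 3) and 22697 ± 2553 CPM (n = 4). The camera adjusted p was 4.82e-05, and the adjusted p = 0.506 with an estimated correlation. The count of lower genes was 13 without knockout replicate 4 and 3 without knockout replicate 2 or any of the wild-type libraries. Ighm fell from 9770 ± 2800 to 4220 ± 573 CPM, the inhibitory receptor gene Cd22 by 0.96 and Fcer2a, which encodes CD23, by 1.42. Of 14 germinal centre B and plasma cell genes, 6 fell and none rose, as when adjusted over the list alone (camera adjusted p = 0.0025, and adjusted p = 0.506 with an estimated correlation). Their summed level was not lower, at 6400 ± 1532 CPM (n = 3) and 7194 ± 4698 CPM (n = 4). The count of lower genes was 3 without wild-type replicate 2. Rgs13, a regulator of G protein signalling, fell from 22 ± 4.51 to 3.53 ± 2.30 CPM. Of 12 CD8 T and natural killer cell genes, 3 fell, among them Cd8b1 by 1.61 and Klrb1c by 1.66, with 5 lower when adjusted over the list alone (camera adjusted p = 0.0413, and adjusted p = 0.549 with an estimated correlation). No member was called without knockout replicate 2, wild-type replicate 1 or wild-type replicate 2, and 1 without knockout replicate 3. The list call ended without wild-type replicate 1 (0.355), without knockout replicate 2 (0.0726) and without knockout replicate 3 (0.0898).

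The myeloid lists did not pass. Of 24 macrophage, monocyte and dendritic cell genes, 1 rose and 2 fell, with 3 and 2 when adjusted over the list alone (adjusted p = 0.553). Xcr1, a receptor of cross-presenting dendritic cells, rose by 1.75, while Cd209a and the integrin gene Itgam fell. Of 15 neutrophil genes, 5 fell and 1 rose, with 6 and 2 when adjusted over the list alone (adjusted p = 0.346). The count of lower neutrophil genes was 2 without wild-type replicate 1, 6 without knockout replicate 4 and 1 without any other single library. S100a8 fell from 2870 ± 631 to 1760 ± 271 CPM and Ltf, which encodes lactoferrin, by 0.77, and the collagenase gene Mmp8 rose by 0.59. Of 8 stromal and endothelial genes, 2 fell, as when adjusted over the list alone (adjusted p = 0.106), Fabp4 by 2.65 and the endothelial cadherin gene Cdh5 by 1.07. This list reached 0.0276 without knockout replicate 1.

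Among the technical lists, all 7 libraries had the pattern of male mice, with at most 11 Xist counts and at least 1753 Ddx3y counts. Of 4 tested sex-linked genes, 2 fell, as when adjusted over the list alone (adjusted p = 0.108), Kdm5d by 0.47 and Ddx3y by 0.35. Of 12 mitochondrially encoded genes only mt-Nd3 fell, as when adjusted over the list alone (list adjusted p = 0.12), and mt-Nd6 had a log2 fold change of -0.23 (adjusted p = 0.352). Without knockout replicate 4 the list reached 0.00508. Of 11 heat shock genes, 3 fell, with 4 lower and 1 higher when adjusted over the list alone (adjusted p = 0.108). They were Hspa1a, Dnaja1, which fell by 0.76, and Dnajb1, which fell by 0.45. This list reached 0.0357 without wild-type replicate 3 and 0.0286 without knockout replicate 1. In an exact permutation test of each list's mean log2 CPM, 10 of the 30 lists reached the smallest possible p of 0.0286, 3 higher and 7 lower, and the adjusted p was 0.0858 for each of them.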

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

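No test in this part was chosen after the result was seen. Some of the values examined, however, were of genes picked only after the data were seen, among them Ighg3. In the 4 libraries labelled knockout, 6 of 153 values examined had 1 library far from the other 3, where chance alone would give about 7.7. Knockout replicate 4 had 255 CPM of the cyclin gene Ccna2, against 181 to 183 CPM in the others, and 4640 CPM of the immunoglobulin gene Ighg3, against 926 to 1080 CPM. Knockout replicate 1 had 9.87 CPM of Ifi44l, against 21.1 to 22.3 CPM, and 0.473 CPM of Fabp4, against 1.56 to 1.84 CPM. Knockout replicate 2 had 0.668 CPM of Gzmk, against 1.06 to 1.12 CPM. The mean log2 CPM of the endoplasmic reticulum protein folding list was 7.18 in knockout replicate 3 and between 7.74 and 7.83 in the others. Groups of 3 are too small for this comparison, so the wild-type libraries were not examined.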

How the results depend on the processing

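The tests of this part chosen only after the results were seen are the medians and counts of called members of each list without 1 library, the fit without erythroid list genes and the fit of replicates 1 to 3 without a block. The count of 2455 genes (1376 higher, 1079 lower) moved with the test and with the number of libraries. limma-voom with quality weights called 3870 genes, 1840 of them lower. A fit to log2(FPKM + 0.1) called 1615, with 658 lower, and a fit to log2(FPKM + 1) with no filter called 1169, with 655 higher and 514 lower. The test against a fold change of 1.5 called 514 genes, 349 higher and 165 lower, since it asks for more than a difference from 0. Leaving out 1 library gave 1050 to 2553 genes, 639 to 1415 higher and 411 to 1138 lower, with fewer samples in each fit. DESeq2 called 3352 genes, of which 2444 were among the 2455. In each of these fits no gene called in common with the reported fit changed direction. No named gene that passed the test changed the sign of its fold change in any alternative, and Eif2s3y, which did not pass, ran from -0.06 to 0.06. The median log2 fold change of the tested genes stayed between -0.032 and 0.012 over the scalings. The fit without the genes of the erythroid lists called 2417 genes, 2412 of them shared.

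The replicate numbers 1 to 3 are shared by both groups, and the labels do not say whether they mark pairs. Correlations of the deviations of same-numbered libraries were -0.048, 0.025 and 0.158, within the range of differently numbered ones, -0.273 to 0.323. With so few libraries, these values cannot exclude an effect of pairs. With a replicate block on the 6 libraries numbered 1 to 3, 2107 genes were called, against 2203 on the same libraries without the block. Under the replicate block the mitochondrially encoded list reached 0.00159 and the heat shock list 0.0481.

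With an estimated correlation, 0 of 30 lists passed in place of 11. The adjusted p was 0.506 for the Tfh, Treg, naive, cell cycle, immediate early, B cell, germinal centre, erythroid and megakaryocyte lists, and 0.549 for the oxidative phosphorylation and CD8 and NK lists. Before adjustment, this camera p ran from 0.0236 (Tfh) to 0.202 (cell cycle) among the lists at 0.506, with 0.0563 for the erythroid list. With fry, 6 lists passed. The calls ended for the naive (0.0596), cell cycle (0.0596), oxidative phosphorylation (0.11), immediate early (0.0988), CD8 and NK (0.199), B cell (0.0617) and germinal centre (0.0617) lists, while the Hippo (0.0295) and stroma (0.0295) lists were called. Leaving out 1 library, adjusted p ran from 0.00202 to 0.355 for CD8 and NK, 0.0276 to 0.152 for stroma, 0.0492 to 0.355 for adhesion, 0.0199 to 0.355 for co-inhibitory, 0.028 to 0.276 for glycolysis and 0.0286 to 0.404 for heat shock. It ran from 0.00508 to 0.351 for mitochondrially encoded, 0.028 to 0.446 for type 1 and 0.0121 to 0.355 for type 2 genes. The counts of called members of the lists that did not pass moved with single libraries too, as in glycolysis with 7 without knockout replicate 3 and 2 without any of the wild-type libraries. Stk4 in CPM by total library size differed by -0.14 on the log2 scale (exact permutation p = 0.0857). Beyond the fewer samples of some fits, the cause of these moves was not tested. At these totals, 3 counts correspond to 0.175 CPM in a wild-type library, which limits folds of genes near that level.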

Other observations

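The tests that weigh explanations in this part, its 10 added lists and their medians without 1 library were chosen after the results were seen, except the counts of splits. The added lists drew finer lines through the same cells. Of 12 germinal centre B cell regulators, 10 were lower and none higher (median log2 fold change -1.24), with Mef2b at 38.3 ± 4.92 CPM in the wild-type libraries and 8.12 ± 1.87 CPM in the knockout libraries. Of 11 marginal zone and follicular B cell genes 2 were lower and none higher (median -0.52, and -0.31 without knockout replicate 4), with 4 lower when adjusted over the list alone. Of these 11, 9 had log2 fold changes below 0, and the difference from the germinal centre list was not tested. Of 12 immunoglobulin constant region genes and the joining chain gene Jchain 2 were lower and none higher. The median of these 13 depended on single libraries, with -0.24 in all, -0.67 without knockout replicate 4 and -0.03 without knockout replicate 3. Ighg1 stood at 2580 CPM in knockout replicate 4 and between 219 and 430 CPM in the other knockout libraries, against 701 to 1200 CPM in the wild-type libraries (edgeR adjusted p = 0.942). Igha stood at 5540 CPM in knockout replicate 4 and between 1820 and 2660 CPM in the others, against 1340 to 2910 CPM (edgeR adjusted p = 0.315).

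Of 12 erythroid regulators and early markers 11 were higher (median 2.95), among them Gata1 with a log2 fold change of 2.94 and the erythropoietin receptor gene Epor with 3.53. Of 13 genes of the red cell membrane skeleton and haem synthesis 11 were higher (median 1.89). None of 15 red pulp macrophage genes passed edgeR's test in either direction, and their median ran from 0.01 without knockout replicate 1 to 0.48 without knockout replicate 4 and 0.55 without wild-type replicate 2. In the fits without knockout replicate 4 and without wild-type replicate 1, 1 of them was called higher. Csf1r, at 529 ± 116 and 713 ± 58.2 CPM, had an unadjusted p of 0.0209. Of 12 conventional dendritic cell genes 3 were higher and 1 lower (median 0.28, with 0.46 without wild-type replicate 1 and 0.18 without wild-type replicate 3). Cd207 rose from 0.196 ± 0.072 to 4.55 ± 2.14 CPM and Zbtb46 by 1.06 on the log2 scale. Of 13 genes of eosinophils, basophils and mast cells 1 was higher and 2 were lower (median 1.02, with 0.36 without knockout replicate 4 and 0.58 without wild-type replicate 2), and none was called without any 1 of the wild-type libraries.

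Chance is argued against for the number of genes called, at the smallest permutation p of the design (0.0286). Of 35 splits of the 7 libraries, 1, the real one, gave as many as 2455, and the highest of the others gave 17. The same held for the genes called higher, where 1 of 35 splits reached 1376 and the highest other gave 8. It also held for those called lower, where 1 of 35 reached 1079 and the highest other gave 9. The other splits mix the groups, which raises the spread within each side. Their low counts are thus not those of libraries without a difference. Chance cannot be excluded for the number of lists called: 13 of 35 splits called at least 11 of the 30 lists, and the highest of the others called 20.

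T cell genes were lower together in the libraries labelled knockout, in RNA that held transcripts of B cells, neutrophils and red cell precursors, which a sort of Tfh cells as in the labels would remove. A difference in scaling of the libraries does not enter the level of T cell genes relative to other genes, since a factor per library cancels there. In unscaled log2 counts, the mean of the 18 pan-T genes less the median of all tested genes differed by -1.76 (exact permutation p = 0.0286). The pan-T list was made after its genes were seen to be lower, so this value restates the pattern and is no separate test. Fewer T cells in a mixed RNA cannot be told apart from lower expression in T cells, since the 17 of 18 pan-T genes that were lower past the threshold are the pattern itself. An added list of 9 tested Tfh genes had 8 lower (median -1.81). Its members Maf (log2 fold change -0.54) and Il4 (0.94) are not restricted to T cells, which limits the comparison with the T cell genes. Whether this list fell beyond the T cell genes cannot be told apart with 7 libraries: the difference of the list means changed by 0.04 (exact permutation p = 0.8). An effect of the genotype on T cell numbers stays open and was not tested.

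Detection in nearly 1 group only, with every library of a group at least 8-fold above every library of the other after adding 0.17 CPM, held for 15 genes on 9 chromosomes, 12 higher and 3 lower. DNA linked to Stk4 is argued against as the whole cause, because 6.7% of them (upper 95% bound 31.9%) lay within 5 Mb of that gene, but it stays open for part of the differences there, since 15 of 94 tested genes in that window were called with at least 1 log2 unit, against 6.9% elsewhere (Fisher's exact p = 0.00323). Reads shared with pseudogenes, or a variant of a gene copy between the mouse stocks, may account for part, since 33.3% were pseudogenes against 5.8% of the other tested genes (Fisher's exact p = 0.0012). These shares were not matched on expression level, so the excess of pseudogenes does not by itself point to either. Linked DNA near the gene with the symbol Mst1 cannot be told apart from other causes for Cpne4, Col6a4 and Rpl29, which lie 3.5, 2.1 and 1.7 Mb from it, because that window was picked after they were seen (Fisher's exact p = 0.000324 for the share within 5 Mb). The sequence of the reads was not analysed here, so a strain difference stays untested.

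Cell cycle genes were higher in the libraries labelled knockout. More germinal centre B cells are argued against as the cause by the median of -1.24 for their regulators, none of which was called higher. More erythroid precursors, which divide, are a candidate explanation, as 13 of the 14 tested members of the fixed erythroid list were higher past the threshold. The most abundant of the globin genes tested, Hba-a1, stood at 29.0 ± 5.67 and 175 ± 71.6 CPM, and Car2 at 36.0 ± 15.2 and 347 ± 110 CPM. Faster division of other cells stays open, and no test here separates it from a change in cell types.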
